A study of Mus musculus with 6 samples.

How the data were processed

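RNA from CD8+ T cells of mouse spleen was sequenced in 6 libraries, 3 from mice on the ND diet and 3 from mice on the CDAHFD diet, each fed for 7 weeks. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made with either a whole-RNA kit or an mRNA kit, without saying which served which library. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, its strand setting and the annotation were not given in the sources used here.

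The authors deposited 1 table of signal values, read counts per gene divided by a factor per library, for 26181 Ensembl gene IDs in 6 columns. Within each column every value was a whole multiple of the smallest value above 0 (100% of values whole within 0.001), so whole reads were recovered by dividing by that step. The steps matched median-of-ratios size factors recomputed from the recovered reads, with a largest relative difference of 2.66e-15. Recovered totals ranged from 25314988 to 28067393 reads per library. Between libraries of 1 diet, counts of genes with at least 20 reads differed by 2.75 to 5.79 times the variance of read sampling (chi-square per degree of freedom), against 66.8 to 74.4 between diets, so no library repeated another. The common biological coefficient of variation, edgeR's name for spread between libraries beyond read sampling, was 4.47%. Despite the name, this spread may be technical, since separate animals are not stated. The columns of the diet group spell its name CDHFD, and they were matched to the CDAHFD samples as the only other group.

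Gene symbols came from a table of Ensembl IDs, which matched 26147 IDs and left 34 without a symbol, 15 of them tested. Among tested genes, 4 symbols occurred more than once. Biotypes and 1-based coordinates came from GENCODE mouse release M21, which uses the same build. Of each named gene, the position is given for a few and the biotype where it matters.

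The main test was limma 3.58.1 (linear model, moderated statistics with a mean-variance trend and robust estimation) in R 4.3.3, on log2(normalised count + 1). It ran on the 15819 genes with a mean of at least 10 normalised counts over the 6 libraries, with diet as the one term and Benjamini-Hochberg adjustment over all genes tested. A gene was called, and is said to have risen, fallen or changed, at an adjusted p under 0.05. Log2 fold changes are on the log2(normalised count + 1) scale, which understates the change of low genes. Values are given as the mean ± SD of 3 libraries, and as means alone where many genes are listed. Where 1 group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group, and with 1 to 3 reads it is a ratio of depth-adjusted reads with an exact 95% binomial interval. These intervals and floors cover counting error only.

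Tested on simulated data drawn for the comparison of CDAHFD with ND, on 15819 genes with 50 genes changed at each fold size, the test recovered 28 of 50 genes changed 1.3-fold, 37 at 1.5-fold, 42 at 2-fold and 50 at 4-fold. It made 7 false calls among 164. A far smaller share of genes changed in the simulation than was called in the data, which makes the adjustment stricter. These recoveries therefore describe the simulated setting. Recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, which left 1 adjusted p as NA. The 7381 genes that limma and edgeR both called had the same direction in both, and 6738 genes were called by limma and DESeq2.

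The 37 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. They cover T cell states, metabolism, chromatin, stress, secreted factors, technical signs and other cell types of the spleen. Each list was tested with camera at a preset correlation of 0.01, which asks whether its genes rank higher or lower than other genes, and beside it with an estimated correlation and with fry, all adjusted over the 37 lists. Named by rule were Trnp1, the 12 largest log2 rises and the 12 largest falls among called genes whose diets did not overlap, and from each list the up to 4 called members with the smallest adjusted p. The ranking left out symbols of predicted genes (Gm and a digit), symbols that end in Rik or in -ps, clone accessions and antigen receptor segments. The symbols 9930111J21Rik2 and Rpl31-ps3 end otherwise, so the rule kept them. Any other gene is said to have been named after its value was seen. Of the genes named by rule, 4 are not reported here.

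The alternatives were another pseudocount (0.5 or 5), no filter or a mean of at least 50, equal totals or trimmed mean of M-values scaling, limma without trend and robust estimation or with sample weights, edgeR, DESeq2, a replicate block, a further 2-fold threshold and each library left out in turn. No sample or column was left out of the main comparison.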

Results

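Messenger RNA levels were measured by RNA sequencing in CD8+ T cells isolated from the spleens of wild-type C57BL/6 mice. The mice had eaten either a diet labelled ND or CDAHFD, the usual short name of a choline-deficient, L-amino acid-defined, high-fat diet that brings on steatohepatitis with fibrosis of the liver, for 7 weeks. Each diet had 3 libraries, and the table held 26181 genes as normalised read counts. The libraries held 25314988 to 28067393 reads assigned to genes, so that a gene at the tested minimum of 10 normalised counts rests on about that many reads per library. A sort gate or purity was not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

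The comparison of CDAHFD with ND asks how the diet changes splenic CD8+ T cells, with Trnp1, the gene named in the title of the series, reported first. Trnp1, which encodes a nuclear protein known from the proliferation of neural progenitors, rose 3.97-fold, from 75.4 ± 8.11 to 302 ± 18.4 normalised counts (SD, n = 3 per diet). Of 30 cytotoxic effector genes 26 rose at the same time, among them Gzmk, from 77.3 to 907, and Ccl5, from 2559.6 to 11454 normalised counts. Cell cycle genes fell, 42 of 46. Which cells these changes came from was not tested. In the same preparations, genes of cells other than CD8+ T cells rose steeply: the macrophage receptor Csf1r went from 3327 to 27030.4, the globin Hba-a1 from 306 to 3179 and the antibody heavy chain Igha from 965 to 27056 normalised counts. B cell and dendritic cell genes moved the other way, with list medians of -0.31 and -0.52 on the log2 scale.

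Of 15819 genes tested with limma, 7449 (47.1%) changed, 3886 being higher and 3563 lower in CDAHFD libraries. Most of these changes were small, since 4501 of the called genes differed by less than 1.5-fold. At 2-fold or more the balance was uneven, with 1491 genes higher and 280 lower, and at 4-fold or more 656 genes were higher and 25 lower. Without adjustment, 8338 genes had p below 0.05. On the same libraries, edgeR's quasi-likelihood test called 7489 genes and DESeq2 6755. The 3 values of one diet all lay on the same side of the 3 of the other for 54.3% of the tested genes, where chance gives 10%. The first principal component held 79.4% of the variance and separated the diets.

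Trnp1 (ENSMUSG00000056596, chromosome 4, 133491100 to 133498550 in mm10) had a log2 fold change of 1.99 (SE 0.13, limma adjusted p = 1.25e-13). All 3 CDAHFD libraries lay above all 3 ND libraries. An exact permutation test of the group labels gave a two-sided p of 0.1, the smallest that 20 regroupings of 3 against 3 allow. The macrophage list rose in the same libraries by a median of 2.88.

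**Figure D1:**
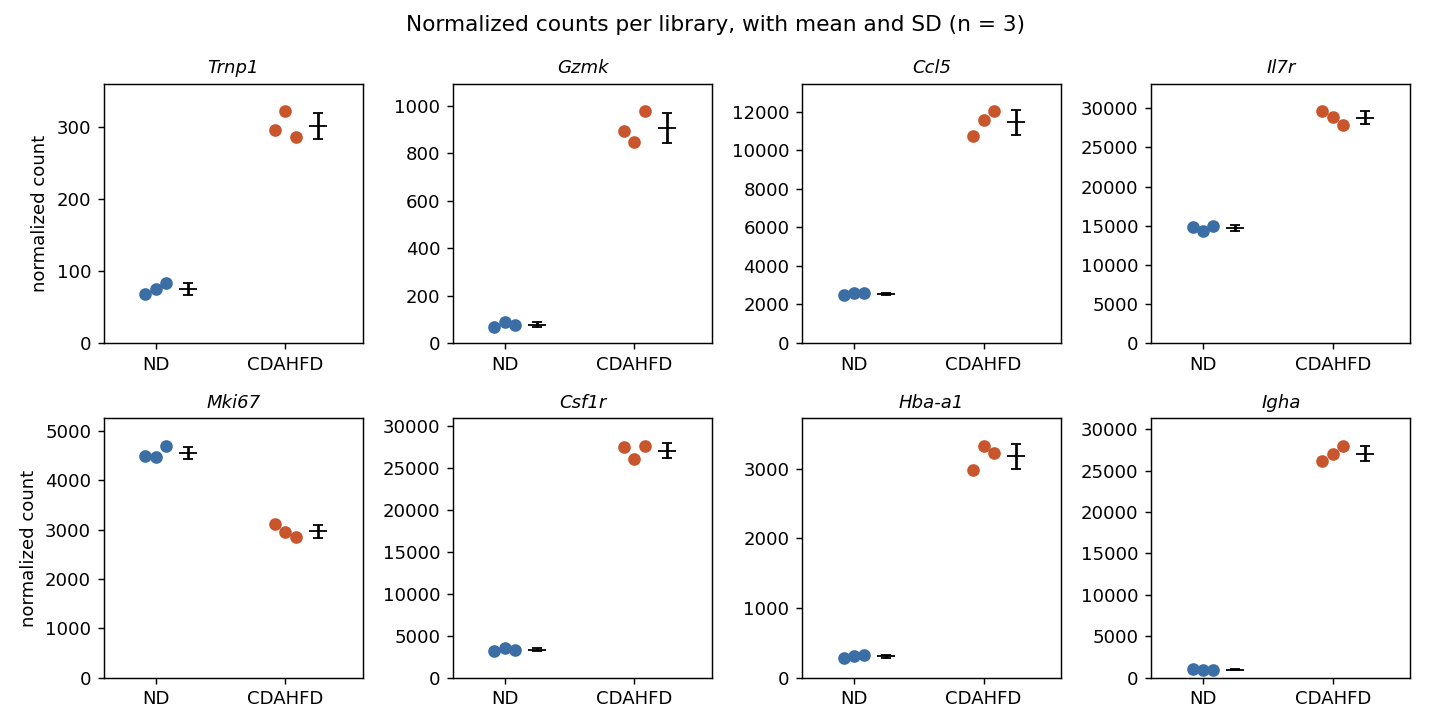
Normalised counts of 8 genes (vertical axes, linear, from 0) in each ND and CDAHFD library, 1 point per library, with the group mean and SD beside the points (n = 3). Trnp1 lies between 287 and 322 in CDAHFD libraries and at 83.9 or less in ND libraries, and Mki67 is the one gene shown that fell.

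The 12 largest rises that the naming rule picks began with genes that were nearly silent in ND libraries. Adamts9 (chromosome 6, 92772699 to 92943492), a secreted metalloproteinase, had 0 reads in the 3 ND libraries and 328 in the 3 CDAHFD libraries, so it was at least 108-fold higher against a floor of 3 reads over the group. Rnf165, with 0 and 89 reads, was at least 29.3-fold higher by the same measure. Frk, a Src-family kinase, had 1 read in ND and 235 in CDAHFD libraries, a ratio of 232 (95% counting interval 41.3 to 9214), and Ppp2r2c had 3 and 191 reads, a ratio of 62.9 (counting interval 21.2 to 308). Lepr, the leptin receptor, rose from 2.85 ± 4.09 to 259 ± 23.7 normalised counts (log2 fold change 6.65, SE 0.84, adjusted p = 0.00201), with ND values that differed widely between libraries. Nos1, the neuronal nitric oxide synthase, rose from 15.2 ± 6.26 to 780.4 ± 48.2 (log2 fold change 5.67, SE 0.26). Nfasc, a cell adhesion molecule, rose from 16.3 ± 0.326 to 777 ± 28.5 (log2 fold change 5.49, SE 0.14). The ephrin receptor gene Epha3 rose from 1.35 to 108 normalised counts. Marco, a scavenger receptor of macrophages, rose from 78.4 ± 7.34 to 3232 ± 109 (log2 fold change 5.35, SE 0.08, adjusted p = 2.58e-28). Ucp3, a mitochondrial carrier induced by fatty acids, rose from 10.3 ± 1.95 to 359.6 ± 25.6 (log2 fold change 5.01, SE 0.19), and Mogat1, which makes diacylglycerol, rose from 1.94 to 76.3 normalised counts. The gene 9930111J21Rik2, an interferon-inducible GTPase-like gene with close paralogues, rose from 95.6 ± 46.4 to 4096 ± 422 (log2 fold change 5.54, SE 0.47, adjusted p = 8.34e-04), and reads may be shared between those copies.

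Among the 12 falls that the naming rule picks, the largest on the log2(normalised count + 1) scale was that of Rps3a2 (chromosome 14, 88123017 to 88123808), an intronless copy of a ribosomal protein gene annotated as a processed pseudogene, from 9394 ± 729.6 to 243 ± 18.5 normalised counts (log2 fold change -5.27, SE 0.06, adjusted p = 8.32e-28). Its parent Rps3a1, named after its value was seen, stood at 58032 ± 2868 and 59371 ± 3945 normalised counts in ND and CDAHFD libraries (adjusted p = 0.592), and reads of such copies are uncertain because the counting could split them. The list of cytosolic ribosomal protein genes, which holds Rps3a1, had a median log2 fold change of -0.20, with 0 of 76 rising. The level parent thus does not exclude that reads moved between the copies. Tpm3-rs7, a related sequence of the tropomyosin gene Tpm3, fell from 7558 ± 139 to 1458 ± 90.6 (log2 fold change -2.38, SE 0.05), with the same uncertainty, which also covers Rpl31-ps3 (from 29.5 to 3.7). Nmnat1 (chromosome 4, 149467572 to 149485202), which makes NAD in the nucleus, fell from 764 ± 57.2 to 103 ± 17.4 (log2 fold change -2.89, SE 0.11, adjusted p = 3.97e-18). Vangl2, a planar cell polarity gene, fell from 217 ± 21.4 to 32.5 ± 7.51. The matrix gene Fbln1 fell from 60.4 ± 10.6 to 8.09 ± 4.66 normalised counts. Low counts lay behind Col5a3, with 111 reads in ND and 3 in CDAHFD libraries (ratio 37.4, counting interval 12.5 to 184), and Mir8099-2, with 73 and 1 (ratio 73.8, counting interval 12.8 to 2956). Wnt10b fell from 25.8 to 4.35, Padi3 from 18.1 to 3.21, Serpinb2 from 60.4 to 11.9 and Mmp12 from 17.3 to 3.02 normalised counts.

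Genes that define T cells fell slightly. Of 20 CD8 T cell identity genes tested, 2 rose, 16 fell and 2 did not pass the test, with 19 called when adjusted over the list alone. The coreceptor chain Cd8b1 fell from 25551 ± 253 to 19151 ± 289.7 (log2 fold change -0.42, SE 0.04, adjusted p = 1.08e-10). Cd3g fell from 10375 to 7525, the receptor constant region Trbc1 fell from 8825 to 6328 and the inhibitory coreceptor Cd5 fell from 4975 to 3571 normalised counts. The identity list had a median of -0.30 (camera adjusted p = 2.46e-06, and adjusted p = 0.119 with an estimated correlation). Macrophage genes rose by a median of 2.88 in these libraries.

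Genes of naive and central memory T cells fell too, and 2 rose of 20 tested, 16 fell and 2 did not pass the test, with 18 called when adjusted over the list alone. Dapl1 fell from 2675 ± 44.5 to 1188 ± 43.5 (log2 fold change -1.17, SE 0.05, adjusted p = 4.14e-18). Rapgef4 fell from 2148 to 1131 normalised counts. Il7r, the receptor for the survival cytokine interleukin 7, went against the list and nearly doubled, from 14683 ± 344 to 28806 ± 850.3 (log2 fold change 0.97, SE 0.04, adjusted p = 1.48e-18). The list's median was -0.27 (camera adjusted p = 7.32e-06, and adjusted p = 0.237 with an estimated correlation). It was no lower than the medians of the CD8 T cell identity list (-0.30) and the B cell list (-0.31). The list median thus shows no loss of naive genes beyond that of T cell genes in general. Cytotoxic effector genes rose broadly: of 30 tested, 26 rose, 2 fell and 2 did not pass the test, with 29 called when adjusted over the list alone. Gzmk, a granzyme of memory and early effector cells, rose from 77.3 ± 10.5 to 907 ± 64.7 (log2 fold change 3.54, SE 0.11, adjusted p = 3.00e-21). The chemokine Ccl5 rose from 2559.6 ± 54.9 to 11454 ± 645 (log2 fold change 2.16, SE 0.04). The activation marker Cd44 rose from 2835 ± 32.2 to 8429.8 ± 462 (log2 fold change 1.57, SE 0.04). The receptor Klrc1 rose from 239 to 1056 normalised counts. Gzma, an effector granzyme named after its value was seen, fell from 474 ± 15.1 to 271 ± 31.3 (log2 fold change -0.81, SE 0.09, adjusted p = 1.68e-08). The effector list's median was 0.85 and its call held under both correlations (camera adjusted p = 3.49e-12, and adjusted p = 0.0298 with an estimated correlation), and 5 of its members are also on lists of other cell types. NK cell genes, with which it shares members, had a median of 0.35, and the macrophage list one of 2.88. The cells behind the effector rises were not tested.

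Most inhibitory receptor genes tested rose as well. Of 19 genes of the list of inhibitory receptors and exhaustion, 13 rose, 2 fell and 4 did not pass the test, with 16 called when adjusted over the list alone. Tigit, an inhibitory receptor, rose from 76.4 ± 4.54 to 401 ± 17 (log2 fold change 2.38, SE 0.11, adjusted p = 2.49e-16). The ectonucleotidase Entpd1 rose from 661 ± 63.9 to 3330.1 ± 189 (log2 fold change 2.33, SE 0.06). Cd38 rose from 1056 to 2434 and the transcription factor Bhlhe40 rose from 286 to 754 normalised counts. Pdcd1, which encodes PD-1 and was named after its value was seen, rose from 85.9 ± 8.3 to 313 ± 20.5 (log2 fold change 1.86, SE 0.12), while Havcr2, chosen likewise, stood at 985 ± 27.9 and 1048 ± 63.7 in ND and CDAHFD libraries (adjusted p = 0.229). The list's median was 0.70 (camera adjusted p = 3.66e-04, and adjusted p = 0.112 with an estimated correlation). Tissue residency genes had a median of 0.32 (camera adjusted p = 1.32e-04, and adjusted p = 0.0589 with an estimated correlation). Of 16 tested, 11 rose, 1 fell and 4 did not pass the test, with 13 called when adjusted over the list alone. The collagen-binding integrin Itga1 rose from 101 ± 14.4 to 539 ± 21.5 (log2 fold change 2.41, SE 0.11). Rgs1 rose from 835 to 2693 and Itgb1 from 5314 to 10606, whereas Itgae, the integrin chain that binds E-cadherin, fell from 6434 ± 54.2 to 3558 ± 171 (log2 fold change -0.86, SE 0.04, adjusted p = 3.20e-16). Among 26 chemokine receptor and migration genes, 17 rose, 6 fell and 3 did not pass the test, with 23 called when adjusted over the list alone, and their median was 0.32 (camera adjusted p = 0.00904, and adjusted p = 0.112 with an estimated correlation). Cxcr3 rose from 1409 ± 111 to 2564 ± 69.2 (log2 fold change 0.87, SE 0.05), while the gut homing receptor Ccr9 fell from 4104 ± 7.52 to 2336 ± 36.9 (log2 fold change -0.81, SE 0.04). The macrophage list rose by a median of 2.88 and the neutrophil list by 1.65 beside these 3 groups.

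Immediate early genes of T cell receptor signalling moved both ways: of 32 tested, 12 rose, 8 fell and 12 did not pass the test, with 23 called when adjusted over the list alone (median 0.05, camera adjusted p = 0.806). Egr1 fell from 2377 ± 11.3 to 1468 ± 85.8 (log2 fold change -0.70, SE 0.05) and Egr3 fell from 1287 to 695, while Fosl2 rose from 794 ± 31.6 to 1473 ± 29.7 (log2 fold change 0.89, SE 0.06) and Klf6 rose from 3316 to 4823 normalised counts. Type I interferon response genes fell on balance. Of 43 tested, 8 rose, 27 fell and 8 did not pass the test, with 35 called when adjusted over the list alone. Ifi27l2a fell from 2860.1 ± 225 to 1169.8 ± 8.83 (log2 fold change -1.29, SE 0.05, adjusted p = 3.92e-18). Oas2 fell from 1136 to 574 and Ifi213 fell from 8667 to 6166, but Ifi44 rose from 73 ± 1.53 to 240.1 ± 24 (log2 fold change 1.70, SE 0.13). That list had a median of -0.25 (camera adjusted p = 5.38e-05, and adjusted p = 0.0756 with an estimated correlation), no lower than that of the CD8 T cell identity list (-0.30). Cell cycle genes fell nearly throughout: of 46 tested, 1 rose, 42 fell and 3 did not pass the test, with 45 called when adjusted over the list alone, and the call held under both correlations (median -0.62, camera adjusted p = 8.45e-14, and adjusted p = 0.0465 with an estimated correlation). The proliferation marker Mki67 fell from 4554 ± 121 to 2967 ± 131 (log2 fold change -0.62, SE 0.04). The topoisomerase Top2a fell from 3395 ± 207 to 1751 ± 25.8 (log2 fold change -0.95, SE 0.05, adjusted p = 4.19e-16). The mitotic kinesin Kif11 fell from 904 to 503 and the kinetochore gene Cenpf fell from 544 to 264 normalised counts. Apoptosis regulators had a median of 0.11 (camera adjusted p = 0.0746), a list that passed the threshold without a filter (adjusted p = 0.0172), without CDAHFD replicate 2 (adjusted p = 0.0441) and by fry (adjusted p = 0.00135). Of 27 tested, 12 rose, 3 fell and 12 did not pass the test, with 15 called when adjusted over the list alone. Fasl, the ligand that triggers Fas, rose from 73.2 ± 8.87 to 370.1 ± 29.8 (log2 fold change 2.33, SE 0.12, adjusted p = 2.60e-15), and the mild rises took in both the survival gene Bcl2 (from 5389 to 7297) and the death-promoting genes Bcl2l11 (from 2460.1 to 3429.6) and Bbc3 (from 782 to 1162). Macrophage genes rose by a median of 2.88 and B cell genes fell by a median of 0.31 in the same libraries. Heat shock genes, a list fixed as a sign of sample handling, rose by a median of 0.65.

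**Figure D2:**
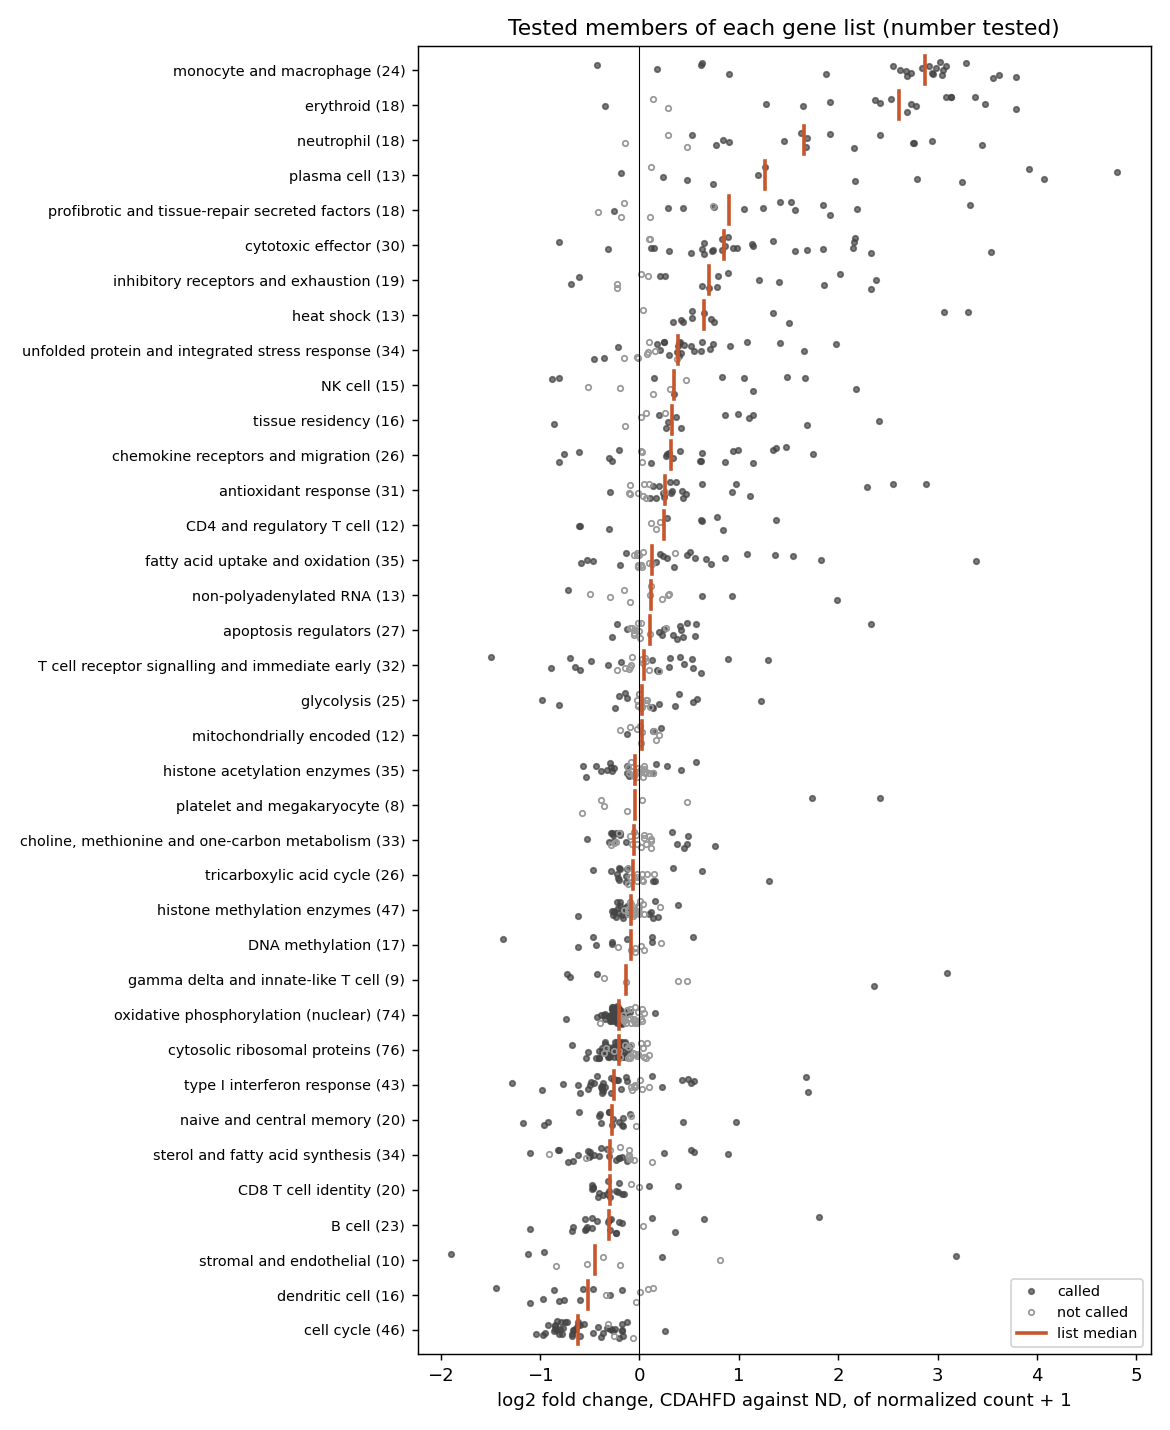
Log2 fold changes of CDAHFD against ND (horizontal axis, from normalised count + 1) of every tested member of the 37 gene lists (vertical axis, ordered by median), with called genes filled, other genes open and the list median as a bar. The medians run from -0.62 for the cell cycle to 2.88 for monocytes and macrophages.

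The metabolic lists that passed the list test went both ways. Fatty acid uptake and oxidation genes ranked higher as a list. Of 35 tested, 16 rose, 5 fell and 14 did not pass the test, with 21 called when adjusted over the list alone (median 0.12, camera adjusted p = 0.0299, and adjusted p = 0.194 with an estimated correlation). The largest rises among the named members were those of the lipid chaperone Fabp4, from 20.3 ± 2.57 to 221 ± 28.6 (log2 fold change 3.38, SE 0.18, adjusted p = 2.64e-15), and of Angptl4, from 138 ± 20.5 to 488 ± 39.9 (log2 fold change 1.82, SE 0.11). The lipid droplet protein gene Plin2 rose from 662 ± 24 to 1936 ± 125 (log2 fold change 1.55, SE 0.06) and the fatty acid transporter Cd36 rose from 926 to 2376 normalised counts. Sterol and fatty acid synthesis genes ranked lower: of 34 tested, 4 rose, 20 fell and 10 did not pass the test, with 26 called when adjusted over the list alone (median -0.30, camera adjusted p = 5.78e-05, and adjusted p = 0.0589 with an estimated correlation). Fasn, the fatty acid synthase, fell from 8118 ± 332 to 5701 ± 111 (log2 fold change -0.51, SE 0.04), whereas the desaturase Fads1 rose from 448 ± 30 to 832 ± 62.2 (log2 fold change 0.89, SE 0.07) and the elongase Elovl5 rose from 4403 to 6429. Nuclear genes of oxidative phosphorylation mostly fell by small amounts. Of 74 tested, 1 rose, 51 fell and 22 did not pass the test, with 55 called when adjusted over the list alone (median -0.20, camera adjusted p = 2.28e-08, and adjusted p = 0.278 with an estimated correlation). Uqcrq fell from 1278 ± 77.6 to 764 ± 50.3 (log2 fold change -0.74, SE 0.06), Ndufb11 from 1924 to 1427, Atp5g2 from 2967 to 2332 and Ndufs1 from 2277 to 1827. The macrophage list rose by a median of 2.88 beside these 3 groups. Neither falling list had a median below those of the CD8 T cell identity list (-0.30) and the B cell list (-0.31). Their medians thus show no fall beyond that of lymphocyte genes in general.

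The other metabolic lists did not pass the list test. Of 25 glycolysis genes, 8 rose, 6 fell and 11 did not pass the test, with 15 called when adjusted over the list alone (median 0.03, camera adjusted p = 0.684). Slc16a3, a lactate exporter, rose from 141 ± 22 to 329 ± 36.8 (log2 fold change 1.23, SE 0.12). Aldoa rose from 7017 to 9226 and Pfkfb3 from 2296 to 2943, while Pfkm fell from 384 to 219. Among 26 tricarboxylic acid cycle genes, 5 rose, 10 fell and 11 did not pass the test, with 17 called when adjusted over the list alone, with a median of -0.06, a mean of 0.01 and a downward test direction (camera adjusted p = 0.262). Cytosolic Idh1 rose from 389 ± 37.8 to 964 ± 68.5 (log2 fold change 1.31, SE 0.08, adjusted p = 1.73e-14) and Aco1 rose from 956 to 1209, while mitochondrial Idh2 fell from 1432 to 1033 and Pdha1 from 3109 to 2551. Of 12 mitochondrially encoded genes, 2 rose, 1 fell and 9 did not pass the test, with 2 called when adjusted over the list alone (median 0.02, camera adjusted p = 0.883). These were mt-Nd2 (from 36659.6 to 42747), mt-Nd4 (from 36800.2 to 40657) and mt-Atp6 (from 1419 to 1297, adjusted p = 0.0403). Without trend and robust estimation mt-Nd4 lost its call (adjusted p = 0.122). The call of mt-Atp6 was lost without ND replicate 1 (adjusted p = 0.0575), 2 (0.16) or 3 (0.0605) or CDAHFD replicate 1 (0.108) or 2 (0.084). It was lost as well without a filter (0.0767), without trend and robust estimation (0.092), with the replicate block (0.0615) and by DESeq2 (0.0804). Choline, methionine and one-carbon metabolism genes, of interest because the diet lacks choline, had a median of -0.05 (camera adjusted p = 0.544). Of 33 tested, 6 rose, 10 fell and 17 did not pass the test, with 18 called when adjusted over the list alone. Chpt1, which makes phosphatidylcholine, rose from 192 ± 9.07 to 327 ± 6.35 (log2 fold change 0.77, SE 0.10). The methionine adenosyltransferase Mat2a rose from 4400.1 to 5543, and the amino acid transport genes Slc3a2 and Slc43a2 rose from 2702 to 3799 and from 3542 to 4946 normalised counts. The macrophage list had a median of 2.88 beside these lists too.

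Of the 3 lists of chromatin genes, 2 passed the list test, both lower and with the preset correlation only. Of 17 DNA methylation genes, 3 rose, 7 fell and 7 did not pass the test, with 10 called when adjusted over the list alone (median -0.08, camera adjusted p = 0.0483, and adjusted p = 0.237 with an estimated correlation). This list lost its call at a mean of at least 50 (adjusted p = 0.0784), without ND replicate 1 (adjusted p = 0.0873) and without CDAHFD replicate 3 (adjusted p = 0.0572). Tet1, which oxidises 5-methylcytosine, fell from 1186 ± 81.5 to 457 ± 48.5 (log2 fold change -1.38, SE 0.07, adjusted p = 7.19e-15). Uhrf1, which recruits the maintenance methyltransferase and is also on the cell cycle list, fell from 1252 ± 11.5 to 815 ± 46.2 (log2 fold change -0.62, SE 0.06). Tdg fell from 1023 to 739 and Gadd45b rose from 479 to 697. Among 47 histone methylation enzymes, 6 rose, 18 fell and 23 did not pass the test, with 24 called when adjusted over the list alone (median -0.08, camera adjusted p = 0.00802, and adjusted p = 0.311 with an estimated correlation). Ezh2, the methyltransferase of Polycomb complex PRC2, fell from 1404 ± 58.6 to 916 ± 11.5 (log2 fold change -0.61, SE 0.05, adjusted p = 1.46e-10), and the demethylases Kdm5a (from 6877 to 5751) and Kdm5b (from 2014 to 1665) and the arginine methyltransferase Prmt1 (from 2429.6 to 2019) fell by less. Of 35 histone acetylation enzymes, 5 rose, 12 fell and 18 did not pass the test, with 17 called when adjusted over the list alone (median -0.04, camera adjusted p = 0.111). The deacetylases Hdac1 (from 4392 to 3245), Hdac5 (from 1975 to 1581) and Hdac7 (from 9118 ± 169 to 6307 ± 647, log2 fold change -0.54) and the acetyl-CoA synthetase Acss2 (from 2015 to 1542) fell. CD8 T cell identity genes fell by a median of 0.30 and macrophage genes rose by 2.88 in the same libraries.

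The 3 lists of stress genes ranked higher with the preset correlation. Of 13 heat shock genes, a list fixed as a sign of sample handling, 12 rose, 0 fell and 1 did not pass the test, with 12 called when adjusted over the list alone (median 0.65, camera adjusted p = 5.36e-10, and adjusted p = 0.0589 with an estimated correlation). Hspa1b rose from 217 ± 2.02 to 2151 ± 54.3 (log2 fold change 3.30, SE 0.06, adjusted p = 6.85e-26) and its near-identical neighbour Hspa1a from 86.9 to 735, a pair whose reads the counting could split, and Hsph1 rose from 2827 to 8047 and Hspa8 from 40904 to 67651. Among 34 genes of the unfolded protein and integrated stress response, 23 rose, 3 fell and 8 did not pass the test, with 26 called when adjusted over the list alone (median 0.39, camera adjusted p = 5.35e-06, and adjusted p = 0.119 with an estimated correlation). Cebpb rose from 298 ± 14.1 to 798 ± 61.7 (log2 fold change 1.42, SE 0.08), Xbp1, which is also on the plasma cell list, rose from 1272 to 2132, and the endoplasmic reticulum chaperones Canx and Hsp90b1 rose from 6566 to 9621 and from 7896 to 12215. For the antioxidant response, 21 rose of 31 tested, 1 fell and 9 did not pass the test, with 24 called when adjusted over the list alone (median 0.26, camera adjusted p = 8.06e-06, and adjusted p = 0.194 with an estimated correlation). Haem oxygenase, Hmox1, which is also a macrophage list member, rose from 2578 ± 57.3 to 15135 ± 855 (log2 fold change 2.55, SE 0.04, adjusted p = 3.12e-27). The ferritin chains Ftl1 and Fth1 rose from 6219 to 13428 and from 10884 to 21364, and Gsr rose from 1108 to 2107. The macrophage list rose by a median of 2.88, the erythroid list by 2.62 and the plasma cell list by 1.27 beside these groups.

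Cytosolic ribosomal protein genes mostly fell slightly. Of 76 tested, 0 rose, 55 fell and 21 did not pass the test, with 58 called when adjusted over the list alone (median -0.20, camera adjusted p = 4.20e-12, and adjusted p = 0.237 with an estimated correlation). Rpl31 fell from 22635 ± 1467 to 15608 ± 415 (log2 fold change -0.53, SE 0.04), Rpl10a from 32602 to 22792 and Rpl41 from 25836 to 19071. The ribosomal median was no lower than that of the CD8 T cell identity list (-0.30). RNAs taken as non-polyadenylated, a list fixed because the labels name both a whole-RNA and an mRNA library kit, had a median of 0.11 (camera adjusted p = 0.684). Whether each member lacks a poly(A) tail was not tested. Of the 52 genes on this list, only 13 were tested. Of these, 3 rose, 1 fell and 9 did not pass the test, with 4 called when adjusted over the list alone. The histone genes Hist1h2bc, Hist1h1c and Hist2h4 rose from 36.1 to 148, from 356 to 549.7 and from 15.2 to 28.3, and H1f0 fell from 267 to 162 normalised counts. Hist2h4 lost its call without ND replicate 2 (adjusted p = 0.127) and without CDAHFD replicate 3 (adjusted p = 0.0732), and also without trend and robust estimation (0.0544) and by DESeq2 (0.0728). In these libraries the macrophage list had a median of 2.88 and the heat shock list one of 0.65.

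Genes of profibrotic and tissue-repair secreted factors ranked higher as a list. Of 18 tested, 12 rose, 1 fell and 5 did not pass the test, with 14 called when adjusted over the list alone (median 0.90, camera adjusted p = 2.50e-04, and adjusted p = 0.0589 with an estimated correlation). The platelet-derived growth factor genes Pdgfc and Pdgfb rose from 20 ± 1.06 to 210.0 ± 16.3 (log2 fold change 3.33, SE 0.18, adjusted p = 2.21e-15) and from 191 ± 13.8 to 570.1 ± 54.6 (log2 fold change 1.57, SE 0.09). Mmp9, a matrix protease that is also on the neutrophil list, rose from 235 ± 23.9 to 886 ± 32.6 (log2 fold change 1.92, SE 0.08). The lectin Lgals3 rose from 1161 to 1954. Tgfb1, named after its value was seen, rose less, from 3884 ± 59.9 to 4733 ± 247 (log2 fold change 0.28, SE 0.04). The macrophage list rose by a median of 2.88 and the neutrophil list by 1.65 in the same libraries.

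Markers of several other cell types rose, and the monocyte and macrophage list had the highest median of the 37. Of 24 monocyte and macrophage genes, 23 rose, 1 fell and 0 did not pass the test, with 24 called when adjusted over the list alone (median 2.88, camera adjusted p = 1.51e-25, and adjusted p = 0.112 with an estimated correlation). The 1 that fell was Ly6c2 (log2 fold change -0.42), while the monocyte receptor gene Ccr2 rose (0.63), both named after their values were seen. The list median does not describe monocytes apart from macrophages. Csf1r, the receptor that macrophages need to survive, rose from 3327 ± 152 to 27030.4 ± 869 (log2 fold change 3.02, SE 0.04, adjusted p = 8.13e-29). Axl rose from 2234 ± 135 to 18617 ± 392, Apoe from 3035 ± 149 to 21801 ± 696 and the complement gene C1qc from 1012 to 7991 normalised counts. Csf1r thus passed Cd8b1, at 19151 ± 289.7, in the CDAHFD libraries, on counts that are not corrected for gene length. Erythroid genes had a median of 2.62 and kept their call with the estimated correlation (camera adjusted p = 1.64e-11, and adjusted p = 0.0298 with an estimated correlation). Of 18 tested, 15 rose, 1 fell and 2 did not pass the test, with 17 called when adjusted over the list alone. Hba-a1 rose from 306 ± 24.2 to 3179 ± 179 (log2 fold change 3.38, SE 0.06), Hbb-bs from 282 to 3150.4, Hbb-bt from 59.4 to 528 and the red cell anion exchanger Slc4a1 from 139.8 to 1221, the globin copies being paralogues between which reads could be split. Among 18 neutrophil genes, 15 rose, 0 fell and 3 did not pass the test, with 15 called when adjusted over the list alone (median 1.65, camera adjusted p = 1.66e-10, and adjusted p = 0.0589 with an estimated correlation). Csf3r rose from 594 ± 46.9 to 3175 ± 134 (log2 fold change 2.42, SE 0.06), Cxcr2 from 104 to 709, S100a8 from 619.6 to 1988 and Hdc from 92.5 to 715. For plasma cells, 11 rose of 13 tested, 1 fell and 1 did not pass the test, with 12 called when adjusted over the list alone, with a call that held under both correlations (median 1.27, camera adjusted p = 3.13e-09, and adjusted p = 0.0349 with an estimated correlation). Igha rose from 965 ± 47.2 to 27056 ± 895 (log2 fold change 4.81, SE 0.04, adjusted p = 2.96e-33), Ighg2c from 414 to 6249, Ighg2b from 355 to 3385 and Jchain from 1095 to 7615. Members that are not antibody genes, named after their values were seen, varied. Sdc1 (log2 fold change 1.27) and Derl3 (1.19) rose and Txndc5 rose slightly (0.23), while Mzb1 (0.11) was not called and Irf4 fell (-0.19).

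Genes of B cells and dendritic cells fell in the same libraries. Of 23 B cell genes, 4 rose, 18 fell and 1 did not pass the test, with 22 called when adjusted over the list alone (median -0.31, camera adjusted p = 7.46e-05, and adjusted p = 0.251 with an estimated correlation). Pax5, the factor that keeps B cell identity, fell from 3447 ± 121 to 2358 ± 12 (log2 fold change -0.55, SE 0.04). Spib fell from 2539 to 1592 and Ighd from 4660.3 to 3196, while the light chain constant region Igkc, which plasma cells also express, rose from 7266 ± 99.8 to 25361 ± 850.1 (log2 fold change 1.80, SE 0.04, adjusted p = 6.46e-25). Among 16 dendritic cell genes, 0 rose, 11 fell and 5 did not pass the test, with 11 called when adjusted over the list alone (median -0.52, camera adjusted p = 2.65e-05, and adjusted p = 0.148 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, fell from 388 ± 18.9 to 143 ± 20.4 (log2 fold change -1.45, SE 0.11) and Flt3 fell from 1755 to 1162, and 2 of the other most clearly changed members, Itgae and Ccr9, are T cell genes as well. NK cell genes ranked higher as a list. Of 15 tested, 8 rose, 2 fell and 5 did not pass the test, with 11 called when adjusted over the list alone (median 0.35, camera adjusted p = 0.00933, and adjusted p = 0.112 with an estimated correlation). Fcer1g rose from 472 ± 5.89 to 2135 ± 82.3 (log2 fold change 2.17, SE 0.06) and Tyrobp from 753 to 2109, both adaptors that myeloid cells share, and Il2rb and Klrk1, which effector T cells share, rose from 10120.1 to 17971 and from 943 to 2077. Ncr1 and Klrb1c, receptors more specific to NK cells that were named after their values were seen, stood at 49.6 ± 16.2 and 34 ± 9.62 (adjusted p = 0.107) and at 82.8 ± 8.81 and 90.9 ± 8.63 (adjusted p = 0.525) in ND and CDAHFD libraries.

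The remaining cell type lists did not pass the list test. Of 12 CD4 and regulatory T cell genes, 6 rose, 3 fell and 3 did not pass the test, with 9 called when adjusted over the list alone (median 0.24, camera adjusted p = 0.282), with Zbtb7b (from 531 to 822) and Ccr4 (from 37.5 to 98.5) higher and Ikzf2 (from 1174 to 769) and Izumo1r (from 768 to 506) lower. Among 9 gamma delta and innate-like T cell genes, 2 rose, 3 fell and 4 did not pass the test, with 5 called when adjusted over the list alone. Their median was -0.14 and the test direction downward (camera adjusted p = 0.991), while the mean was 0.44, because Tcrg-C2 and Tcrg-C4, constant regions of the gamma chain with similar sequences, rose from 96.9 ± 23.5 to 822 ± 10.1 (log2 fold change 3.10, SE 0.12, adjusted p = 4.47e-15) and from 60 ± 10.8 to 308 ± 3.23. Cd163l1 fell from 657 to 394 and Blk, also on the B cell list, from 1246 to 924. Of 8 platelet and megakaryocyte genes, 2 rose, 0 fell and 6 did not pass the test, with 2 called when adjusted over the list alone, namely Vwf (from 139 to 463) and Clec1b (from 62.9 to 333). That list's median was -0.05, its mean 0.40 and its test direction upward (camera adjusted p = 0.418). Among 10 stromal and endothelial genes, 2 rose, 3 fell and 5 did not pass the test, with 5 called when adjusted over the list alone (median -0.45, camera adjusted p = 0.806). Stab2, a scavenger receptor of sinusoidal endothelium, rose from 270.0 ± 20.8 to 2461 ± 119.7 (log2 fold change 3.19, SE 0.07) and Pecam1 rose from 4513 to 5297, while Kdr fell from 114 ± 16.8 to 31 ± 10.3 (log2 fold change -1.89, SE 0.22) and Sparc from 27.6 to 12.4.

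**Figure D3:**
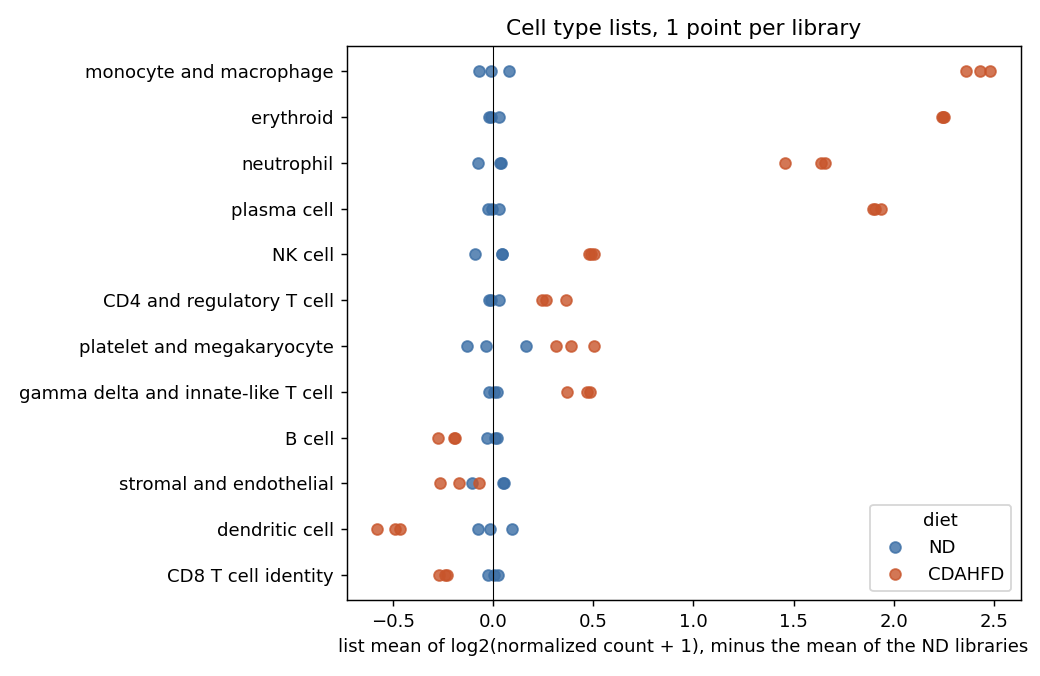
Mean of log2(normalised count + 1) over the tested members of each cell type list in each library, minus the mean of the 3 ND libraries (horizontal axis), for 12 lists (vertical axis), 1 point per library. All CDAHFD libraries lie above all ND libraries for the macrophage, erythroid, neutrophil and plasma cell lists and below them for the CD8 T cell, B cell and dendritic cell lists.

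In total, camera with the preset correlation called 25 of the 37 lists, 14 higher and 11 lower. With an estimated correlation 4 lists passed: cytotoxic effector, cell cycle, plasma cell and erythroid.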

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

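Among the alternatives, trimmed mean of M-values scaling for the lists and leaving out members shared with lists of other cell types were chosen after seeing the data. Both called 25 lists, like the main test. Trnp1 kept its direction and its call under every alternative run, with a log2 fold change of 1.92 to 2.07 when a library was left out and an adjusted p of at most 6.81e-05. The count of changed genes ran from 6105 (limma without trend and robust estimation) to 7836 (sample weights) under other settings. It ran from 6608 to 7509 when a library was left out, with 3574 to 3810 higher and 2981 to 3699 lower. Asking for at least 2-fold in addition left 1771 genes, 1491 higher and 280 lower, by construction of that threshold. The median log2 fold change of all tested genes stayed between -0.04 and 0 under each scaling. A replicate block called 7250 genes (3806 higher, 3444 lower) and 25 lists. No pairing by number was seen: deviations of same-numbered libraries from their group means correlated by 0.04, -0.05 and 0.06, and 3 of 6 libraries correlated best with their own number. With 3 libraries per diet this does not exclude a pairing.

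Of 37 lists, 25 were called in the main test, 24 to 26 with a library left out, 4 with an estimated correlation in place of the preset one, and 32 by fry, which does not compare a list with other genes. Lists lost their call in 24 combinations of list and setting, 21 of them with the estimated correlation, and gained one in 9, 7 of them by fry. No called list changed direction. Lists without a call did: the gamma delta list turned upward with a pseudocount of 5 (adjusted p = 0.997), without a filter (0.921), at a mean of at least 50 (0.948), with equal totals (0.952), with the replicate block (0.94), by fry (0.00624) and without ND replicate 1 or 2 or CDAHFD replicate 2 (0.89 to 0.994 over all left-out libraries). Without a filter the stromal and endothelial list turned upward (0.829) and the non-polyadenylated list downward (0.829), and fry turned the stromal and endothelial list (0.00134) and the choline, methionine and one-carbon list (0.656) upward. The mitochondrially encoded list turned downward without ND replicate 1 or CDAHFD replicate 1 (adjusted p 0.642 to 0.932 over all left-out libraries). The cause was not tested. Of 166 named genes besides Trnp1, none changed direction, and 3 lost their call under some setting, mt-Atp6, mt-Nd4 and Hist2h4, in 14 combinations of gene and setting. In the simulation, 28 of 50 genes changed 1.3-fold were recovered, but it gave 164 calls against 7449 in the data. The adjustment was thus stricter there, and the recovery does not measure that of the main test. A missing call still does not show that a gene was unchanged.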

Other observations

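The genes in this paragraph and the next were named after their values were seen. Several are known from the red pulp macrophages of the spleen and other tissue macrophages. Itgad, an integrin chain of red pulp macrophages, rose from 932 ± 52.5 to 10819 ± 425 normalised counts (SD, n = 3; log2 fold change 3.54, SE 0.05), and Cd5l, an inhibitor of apoptosis that macrophages secrete, rose from 917 ± 42.7 to 7799.6 ± 571 (log2 fold change 3.09, SE 0.05). The mannose receptor Mrc1 rose from 1417 to 16145, Sirpa from 1735 to 11851, the lectin Fcna from 911 to 7034, the complement gene C6 from 332 to 3715 and the protease inhibitor Slpi from 336 to 4198. The lysosomal protease gene Ctsb rose from 9214 ± 479 to 54459.6 ± 2852 (log2 fold change 2.56, SE 0.04), Psap rose from 48314 to 80815 and the uptake receptor Lrp1 rose from 2846 to 21405. Acot1, a fatty acyl-CoA hydrolase induced by fatty acids, rose from 23.7 ± 2.04 to 433 ± 34.7 (log2 fold change 4.13, SE 0.15).

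Of 151 immunoglobulin V segments tested, 117 rose, 4 fell and 30 did not pass the test, with a median log2 fold change of 1.31 and quartiles of 0.76 and 1.95. Of 86 T cell receptor V segments, 2 rose, 28 fell and 56 did not pass, with a median of -0.41, and of 50 J segments 2 rose, 13 fell and 35 did not pass. Among 11 immunoglobulin constant regions, 7 rose, 3 fell and 1 did not pass. Segments of 1 family are similar in sequence, so reads could not be assigned to each with certainty.

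All tests below, except that of the held-out macrophage genes, were chosen after the result was seen, and the held-out list itself was written after the fixed macrophage list had been seen to rise.

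The first pattern is the joint rise of macrophage, erythroid, neutrophil and plasma cell genes in libraries prepared as CD8+ T cells. A smaller share of CD8+ T cells that raised every other cell type alike is argued against by the B cell list. Its median was -0.31 (quartiles -0.53 and -0.19), while the macrophage list stood at 2.88. The dendritic cell list, at -0.52, adds less, because its members Itgae and Ccr9 are T cell genes as well, though Siglech and Flt3 also fell. More macrophage RNA in the CDAHFD preparations was tested on 24 further macrophage genes not on any list, of which 22 rose and 1 fell, with a median of 1.15 (quartiles 0.96 and 1.85), and abundant members such as Ctsd (from 5351 to 12831) and Grn (from 2348 to 6317) rose, though lymphocytes express some of them. Macrophages may thus have contributed more RNA to the CDAHFD preparations, although an enrichment for CD8+ T cells would be meant to remove them. Red cell precursors, neutrophils and plasma cells may have done so too. They were not tested on further genes, and their lists are part of the pattern itself. Whether the diet enlarged these populations in the spleen or the isolation carried over more of them was not tested.

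The second pattern is the rise of Trnp1 itself. Macrophage RNA as a source of the added Trnp1 reads was tested by placing its log2 fold change of 1.99 (SE 0.13) among 48 macrophage genes, the fixed and the held-out ones together. It lay at percentile 50, inside the range from the 10th to the 90th percentile of 0.49 to 3.07. By the same measure Trnp1 lay inside the range of the cytotoxic effector list (0.11 to 2.16) and of 9 of the 37 lists in all. Those lists include the plasma cell, neutrophil, erythroid and heat shock lists. Ranges this wide cannot name the source of the added reads. Macrophage RNA, RNA of other cells and higher expression in the T cells under the diet thus cannot be told apart here.

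The third pattern is a set of 25 genes that fell at least 4-fold, among them Rps3a2 (from 9394 to 243), Tpm3-rs7 (from 7558 to 1458), the long noncoding RNA Gm47015 (from 7671 to 849), Nmnat1 (from 764 to 103) and Gm48358 (from 194 to 0.631). Reads of processed pseudogenes assigned differently in the 2 groups, as the source of most of the falls, are argued against by the annotation, since 3 of the 25 genes are processed pseudogenes. A single genomic block that differs between the mice of the 2 groups, as the source of most of the falls, would hold most of the genes on 1 chromosome, yet they lie on 14 chromosomes, with at most 4 on any of them. Single variants or several small blocks that differ between the mice, copies that share reads with a parent gene, and a response to the diet stay open and may differ from gene to gene.

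Of the 10 ways to split the 6 libraries 3 against 3, 1, the split by diet, called as many as 7449 genes, and the highest of the others called 0. Every other split mixes the diets in each group, so the difference between diets widens its spread within groups. The 0 calls therefore do not bear on chance. The number of splits is also too small for a share under 0.05.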
